A study of Escherichia coli with 3 samples.

How the data were processed

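RNA was extracted from Escherichia coli and sequenced in 3 libraries. Per the labels' protocols, RNA was treated with DNase and fragmented with zinc ions, the fragments were recovered from a denaturing gel, and their ends were repaired with polynucleotide kinase. The Illumina libraries were made with a kit for small RNA and read on a HiSeq instrument, and the Nanopore library was made from RNA to which a poly(A) tail had been added. The protocol text of the Nanopore sample repeats the Illumina steps word for word, so which of them it went through is not settled by the labels. The aligner, the counting and any normalization are not given in the sources used here. Nothing in the labels says how many cultures were grown.

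The file deposited for each library is a GenBank flat file. Per the file headers it holds the complete genome of strain BL21(DE3) as its own submitters sequenced and annotated it. The authors of the RNA study left no value of their libraries in it: it has no count, coverage, score or other measurement, and the depth of the libraries is unknown here. The files were compared byte for byte, after removal of blank space and letter case, and by sequence alone. Each line was then assigned to the header, the features or the sequence. The comparisons between libraries planned for values per gene (the 2 Illumina libraries, sfgfp across platforms, and the share of the reporter) were not run, since they need such values. No test across libraries was made, and no p-value, interval or detection limit for a library is given.

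The record was read with Biopython 1.88 under Python 3.11.15 and NumPy 2.4.6, and figures were drawn with matplotlib 3.10.9. Coverage by a class of features was computed with overlapping features merged. A gene of a list was called found when its name, or an older name fixed with the list, stood in a gene field, letter case ignored. Whole-word matches in the product field were an alternative, as was a match through the K-12 locus tag that the record notes for 3822 of its 4196 coding sequences (91.1%) or through synonyms of a gene table of strain K-12 MG1655 (assembly ASM584v2), from which 4031 of 4651 genes matched. That table was used for names and gene order only. The K-12 match and the words sought in the product field were set after the record was seen, the latter once it was known which members lacked a gene name. The record has no field of synonyms. Genes were named by a rule fixed before the data were examined: all members of the lac, arabinose, T7, CRISPR-Cas and protease lists, and of each other list the 6 found members with the longest features. tufA, tufB, lon, araB, araC, T7 RNA polymerase and the lac genes were chosen for the window shares after the record was seen, as were relE, chpB, elaC, micF, dsrA and mgrR, named because no gene name matched them, the genes beside the CRISPR arrays, ECD_02621 and the K-12 genes named by runs.

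Reporter and T7 polymerase sequences were sought by annotation and by exact protein motifs over 6 reading frames, and the T7 promoter consensus by sequence with up to 4 mismatches. CRISPR arrays were sought as words of 23 bases that recur 50 to 75 bases apart. The commonest word was lengthened while its count did not fall, and its copies were counted exactly and with up to 2 or 4 mismatches on both strands. This replaced the planned search with an annotated repeat, since the record annotates none, and was chosen after the record was seen. A window was called repeated when its exact sequence occurred again on either strand of the circle, for windows of 50 bases, with 25 and 100 as alternatives, all chosen after the record was seen. The longest open frame was the longest stretch of codons without a stop in any of the 6 frames. The searches for windows, arrays, open frames and runs were tested on simulated sequence with planted repeats, arrays and frames, and 12 of 12 checks returned what had been planted.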

Results

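The study sequenced RNA from Escherichia coli grown in LB to logarithmic phase that carried a reporter transcript with a repeat tag. There were 3 libraries, 1 in each group. The first held RNA from cells with repeat-tagged sfgfp, the gene of superfolder green fluorescent protein, read on an Illumina instrument, with the phage T7 promoter named in its labels. The second held RNA from cells with repeat-tagged lacZ-α, the part of lacZ that encodes the amino-terminal complementing peptide of beta-galactosidase, also read on an Illumina instrument, with the arabinose-inducible pBAD promoter named. The third held RNA from cells with repeat-tagged sfgfp read as direct RNA on a Nanopore device after a poly(A) tail had been added, again with pBAD named. The design thus pairs sfgfp with lacZ-α on one platform and sfgfp with sfgfp across platforms. In the first pair the reporter and the named promoter differ together, and in the second the platform and the named promoter differ together, as far as the labels are right: whether sfgfp was under different promoters in its 2 libraries or a label is in error was not settled here.

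The processed files of the 3 libraries hold no measurement of RNA. All 3 pairs of files were identical byte for byte, and each file is the annotated GenBank record of the E. coli BL21(DE3) chromosome. Each had 9882596 bytes, made up of 48 header lines, 75560 lines of features and 75984 lines of sequence, with 0 lines of any other kind and 0 of 18 kinds of annotation field holding a read count, a coverage or a score. No read count, depth, fold change or error of any library can therefore be given, and neither pair of libraries could be compared. The labels give the organism and name no strain, so BL21(DE3) is taken as the host from the record alone. The values below describe the chromosome in the record: loci that bear on the reporters and promoters, its CRISPR repeats, and fixed lists of host genes. All coordinates are those of this record, counted from 1, and the values carry no replicate error because they are read from a sequence.

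The record is a single circular chromosome of 4558953 bp with 50.8% G+C and 0 ambiguous bases. It annotates 4196 protein-coding sequences, 85 tRNA genes, 22 rRNA genes, 65 non-coding RNAs, 1 tmRNA and 70 pseudogenes. Together these cover 89.0% of the sequence, of which protein-coding sequences alone cover 86.5%. The rRNA genes, whose products dominate total bacterial RNA, take up 0.704% of the sequence in 7 copies of 16S, 7 of 23S and 8 of 5S. Of the coding sequences, 2028 lie on the plus strand and 2168 on the minus strand. The non-coding RNAs include 37 filed as antisense RNA, 1 RNase P RNA, 1 signal recognition particle RNA and 26 of other kinds. Prophages and phage-like elements number 9 and occupy 158690 bp, or 3.48% of the record, the longest of them being DE3 at 42940 bp (748396 to 791335).

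Of the reporters, lacZ-α has counterparts in the chromosome and sfgfp has none. Each of 3 short protein motifs of green fluorescent protein was found 0 times in the 6 reading frames, and 0 coding sequences are named for a fluorescent protein. Both LacZ motifs were found at 2 loci. One is lacZ of the lac operon, encoding beta-galactosidase (332766 to 335840, minus strand, 3075 bp). The other is a pseudogene of 450 bp inside DE3 (749941 to 750390, plus strand), annotated as an amino-terminal fragment and equal to 14.6% of the length of lacZ. From the start codon the fragment and the operon gene are identical over 440 bases, or 146 whole codons, and the last 10 bases of the fragment all differ.

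DE3 carries the T7 expression system in the same stretch, and this is the host component on which a T7 promoter depends. A second lacI, the gene of the lac repressor, lies at 748736 to 749818 and is identical to lacI of the operon (335963 to 337045) at all 1083 bases, with 0 mismatches. The 122 bases between lacI and lacZ differ between the copies at 4 positions. Counted from 1 at the first base after lacI, with the operon base first and the DE3 base last, these are G19A, G76A, T77A and A84G. The lacUV5 promoter, which drives T7 RNA polymerase in DE3, is known to differ from the lac promoter at a pair of adjacent bases of its Pribnow box. The gene of T7 RNA polymerase (750421 to 753072, 2652 bp, entered under the gene name of its phage) starts 30 bases after the lacZ fragment, and both of its protein motifs were found at 1 locus. The whole cassette lies within int, the phage integrase gene, which is annotated as a pseudogene (748484 to 754003). The T7 promoter consensus TAATACGACTCACTATAG was found 0 times exactly and 0 times with up to 2 mismatches. With up to 4 mismatches it was found 13 times, against 36 copies expected by chance in a sequence of equal base shares.

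**Figure D1:**
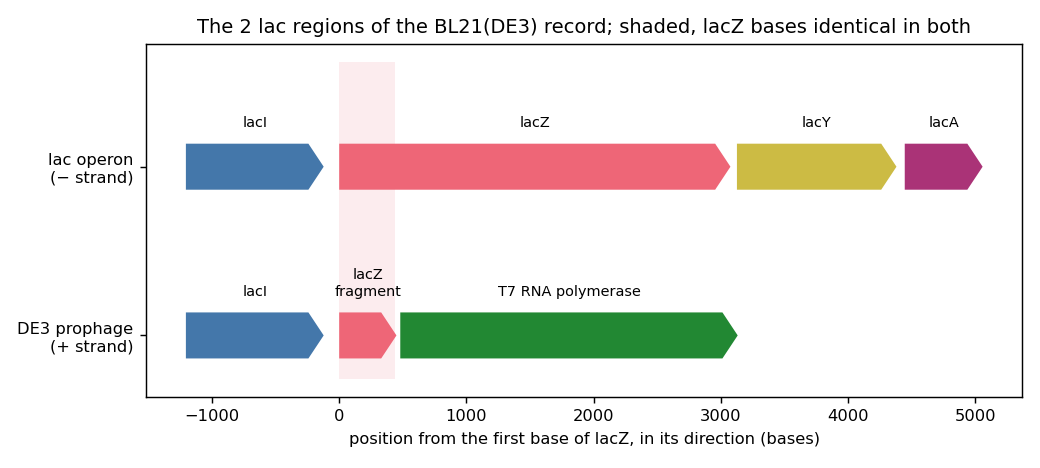
Map to scale of the lac operon (upper track, minus strand turned round) and the start of the DE3 prophage (lower track, plus strand), in bases from the first base of lacZ. The shaded band marks the 440 bases of lacZ that are identical in both. lacI is the same length in both, and T7 RNA polymerase follows the lacZ fragment after 30 bases.

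All 9 listed genes of arabinose uptake and use were found by name. They include araC, the activator of the regulon, which also acts on pBAD (73192 to 74070), and araB (71153 to 72853), araA (69640 to 71142) and araD (68660 to 69355), which encode the enzymes of arabinose catabolism. The 338 bases between araC and araB hold the native form of the promoter. The transporter genes araE (2819046 to 2820464), araF (1930281 to 1931270), araG (1928697 to 1930211) and araH (1927696 to 1928682) and the putative transporter gene araJ (376699 to 377883) were also annotated. The remaining members of the lac operon list, lacY for lactose permease (331461 to 332714) and lacA for thiogalactoside acetyltransferase (330784 to 331395), were found, which makes 4 of 4.

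The record held CRISPR repeats and annotated none of the listed cas genes. CRISPR repeats are short repeats separated by spacers, from which a Cas protein processes guide RNAs. Of the 8 genes of the type I-E system (cas1, cas2, cas3, casA, casB, casC, casD and casE), 0 were found by gene name, older name or product. The record annotates 0 repeat regions. A search for evenly spaced repeats found a 26-base core, GGTTTATCCCCGCTGGCGCGGGGAAC, in 17 exact copies. Copies numbered 19 with up to 2 mismatches and 21 with up to 4. They lie in 3 arrays, all on the plus strand, and 61 to 62 bases separate the starts of neighbouring units. The first array has 5 units (2717669 to 2717938) and lies beside iap. The second has 2 units, each with 3 mismatches (2735582 to 2735668). The third has 14 units (2736175 to 2736994) and lies before queE. The 18 spacers were all distinct, and 0 of them had another copy in the chromosome with up to 5 mismatches. The sequence of the repeat tag on the reporters is not given in the sources used here, so it was not compared with these units.

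**Figure D2:**
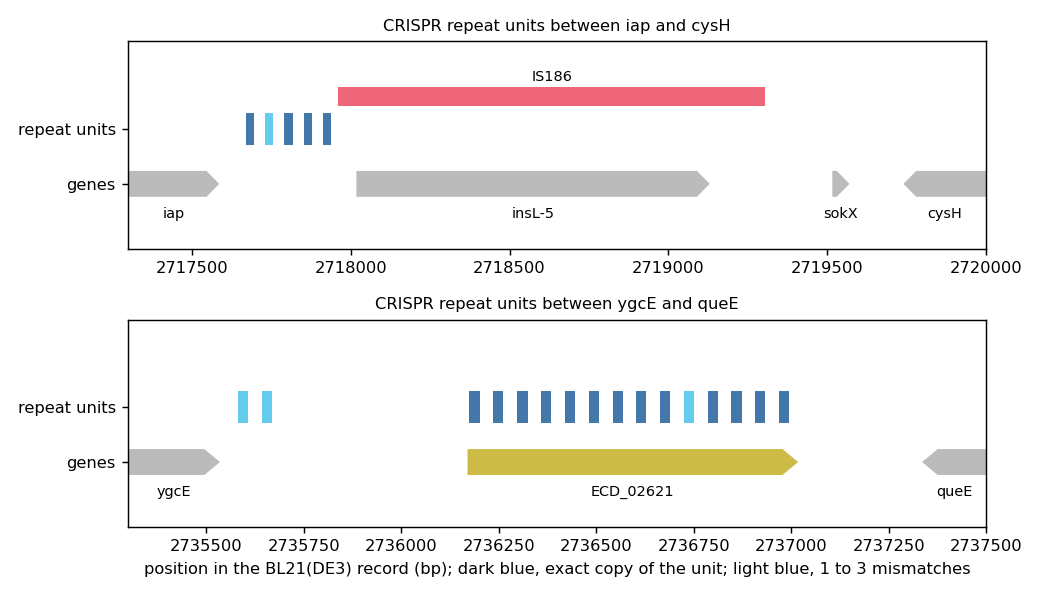
Maps to scale of the CRISPR loci, with position in the record in bp on the horizontal axis, annotated genes as arrows and repeat units as blue boxes (dark, exact; light, 1 to 3 mismatches). The upper map shows 5 units beside IS186, and the lower map shows 14 units inside the annotated coding sequence ECD_02621.

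Genes of RNA decay and of the heat shock response were nearly all found by name. A match by name does not show that a gene is intact, which was not examined for these lists. Of 29 listed genes of RNA decay, 26 were found by name. The longest were rne for RNase E, the main endonuclease of mRNA decay (1143749 to 1146934), rnr for RNase R (4313174 to 4315615), pnp for polynucleotide phosphorylase (3177532 to 3179667), rnb for RNase II (1333345 to 1335279), rng for RNase G (3257482 to 3258951) and pcnB for poly(A) polymerase (160581 to 161945). The toxin genes relE and chpB were not found, and elaC was found only under its other name rbn. All 16 heat shock genes were found, the longest being clpB (2598115 to 2600688), lon (427922 to 430276), ftsH (3193500 to 3195434), dnaK (12161 to 14077), htpG (464166 to 466040) and groL (4278111 to 4279757).

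Of the 3 genes on the protease list, 1 was found by name. ompT, encoding an outer membrane protease, was not found, nor was its relative ompP, which is known from the F plasmid. lon, encoding the ATP-dependent protease La, is annotated as an uninterrupted coding sequence of 784 codons. An IS186 insertion sequence of 1343 bp (426481 to 427823) ends 98 bases before the start codon of lon. B strains are known to lack Lon activity because of an insertion sequence at its promoter.

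Stable and small RNAs were found for 21 of 24 listed members. The longest were rnpB, the RNA of RNase P (3136410 to 3136786), ssrA, the tmRNA that rescues stalled ribosomes (2621995 to 2622357), csrB (2756746 to 2757105) and csrC (3957773 to 3958026), which bind the regulator CsrA, sgrS (80172 to 80398) and glmZ (3876678 to 3876884). micF, dsrA and mgrR were not found. All 54 listed ribosomal protein genes were found, the longest being rpsA (967085 to 968758), rplB (3311713 to 3312534), rpsB (192717 to 193442), rplA (4086930 to 4087634), rpsC (3310352 to 3311053) and rplC (3313467 to 3314096). All 11 translation factor genes were found, among them infB (3181841 to 3184513), fusA (3331001 to 3333115), prfC (4527789 to 4529378), tufA (3329746 to 3330930), tufB (4083995 to 4085179) and prfB (2866044 to 2867142). Over the 10 lists, 145 of 162 entries were found by gene name, with a gene on 2 lists counted on each.

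How far a read from one of these loci can be placed depends in part on whether its sequence occurs elsewhere in the record. Matches to the reporter constructs were not counted in the shares below, so a locus without repeated windows may still share sequence with a construct. Over the whole chromosome 2.35% of windows of 50 bases occurred more than once on either strand. The share was 98.6% in rRNA genes, 86.2% in insertion sequences, 65.0% in tRNA genes and 1.47% in coding sequences. In lacI it was 100.0% at both loci. In the lacZ fragment of DE3 it was 97.5%, or 391 of 401 windows, and in lacZ of the operon it was 12.9%, or 391 of 3026 windows. T7 RNA polymerase had 0 repeated windows of 2603, araB 0 of 1652, araC 0 of 830 and lon 0 of 2306. The genes tufA and tufB, which encode nearly identical copies of elongation factor Tu, each shared 68.8% of their windows.

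**Figure D3:**
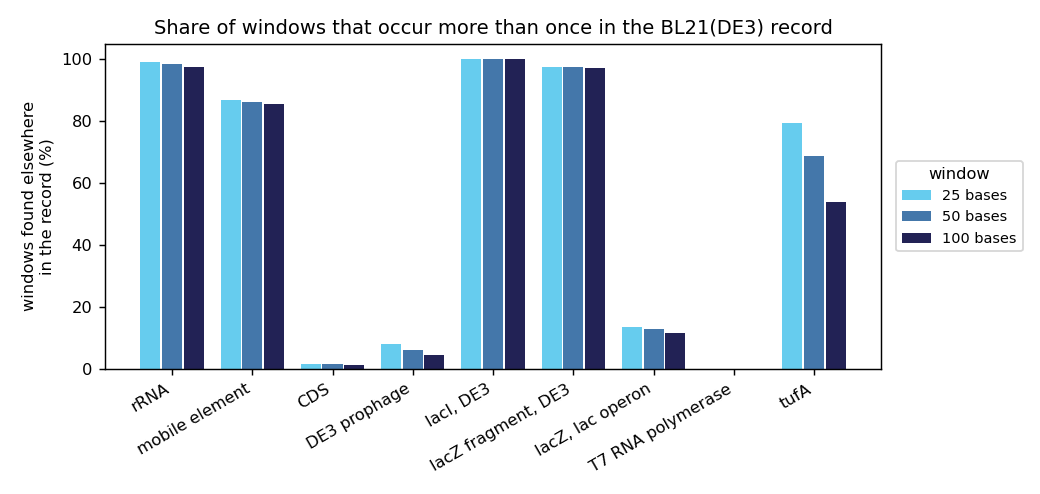
Share of windows, in percent, that occur more than once in the record, for windows of 25, 50 and 100 bases (light to dark bars). lacI and the rRNA genes lie near the top at each window length, the lacZ fragment of DE3 at 97.5% for 50 bases, and T7 RNA polymerase at 0.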

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

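Of 71 alternative values, 64 stayed within 1.5 times that of the main setting, or equalled it where it was 0. Some of these could hardly move, such as window shares of 0 or 100.0% and list counts that only add a way of matching. The files were identical in 3 of 3 pairs under each way of comparing them, genes covered 87.5% without pseudogenes and 89.4% when summed over classes, and list members found numbered 146 with product words and 147 with K-12 names. LacZ moved from 1 annotated coding sequence to 2 loci by motif, because the copy in DE3 is entered as a pseudogene. CRISPR repeats moved from 0 annotated to 17 exact copies, 19 with up to 2 mismatches and 21 with up to 4, because the record annotates none. Those CRISPR counts, the K-12 names and the repeated windows at 25, 50 and 100 bases were chosen after seeing the data. Repeated windows in non-coding RNAs were 0.0705% at 50 bases, 3.43% at 25 and 0 at 100. The protease list rose from 1 to 2 found with K-12 synonyms, but the added match is ompX, which carries ompP as an old synonym. The alternatives planned for values per gene (scaling, count minimum, reporter share) for a field of gene synonyms and for copies of an annotated CRISPR repeat were not run, since the record has none of these. No paired analysis was possible because each group has 1 library and the result comes from no test. The files carry no reads, so nothing can be said of what depth limits.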

Other observations

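The tests on runs of absent genes and on open frames, and the search for direct repeats with a limited shift between the ends of IS186, were chosen after the results they bear on had been seen. The bounds for direct repeats anywhere in the flanks of IS186 were set before. Against the K-12 gene table (assembly ASM584v2), 620 of 4651 K-12 genes had no counterpart by locus tag, symbol or synonym, 488 of them protein-coding. Sequences were not compared, so some of these genes may be in the record under other names. insL1 and insL2 count as absent, yet the record has IS186 copies where K-12 has these genes, after dnaJ and after hokE. Other insertion sequence genes count as absent too, some of them within the runs below. The longest run of neighbours without a counterpart had 40 genes, from fliD to yedS. It holds the flagellar genes fliE to fliR, dcm for the cytosine methyltransferase and the small RNA gene dsrA. A run of 19 genes from paaZ to insI2 holds the phenylacetate degradation genes paaA to paaK. ompT lies in a run of 10 genes from aaaD to nfrB, and the 8 cas genes form a run of their own between iap and sokX.

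These absences may reflect segments that differ between the strains rather than scattered gene names that failed to match. Scattered name mismatches would leave few long runs. Of the absent genes, 322 (51.9%) lay in 25 runs of 5 or more, whereas the highest of 10000 random placements along the K-12 order put 15 there (one-sided permutation p = 0.0001, the smallest these placements can give). This argues against scattered mismatches as the whole cause, and leaves open the 298 genes outside such runs. Names that failed to match in blocks would give long runs too, so the placements cannot tell them from differing segments.

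Whether the annotation left out cas genes that the sequence holds stays open for the record as a whole. Between iap and cysH the longest open frame outside annotated genes had 90 codons. The longest stretch free of annotated genes there is 431 bases, too short for a frame of 200 codons, so its length decided the search for one that long. The value of 90 codons does show that no longer gene lies there whole and clear of annotated genes. A gene of 90 codons or fewer, or one that overlaps an annotated gene, was not excluded. The rest of the record was not searched for cas sequences. The interval between iap and cysH is 2153 bp long (2717587 to 2719739), and 62.4% of it is an IS186 element (2717961 to 2719303) that begins 22 bases after the last repeat unit of the first array, which leaves 810 bases outside the element.

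A plain insertion of IS186, which leaves a direct repeat on both sides, may account for the copy before lon. Its flanks, read from 15 bases outside to 12 bases inside each annotated end, shared 13 bases, GGGGAAACATCCC. At least 7 had been set as a repeat and 5 or fewer as none. The copies after dnaJ, hokE and yeaR shared 12, 12 and 11 bases. Each of these matches takes in a few bases of the element at both ends, so fewer bases than given lie outside it. Counted outside the element alone, the matches after dnaJ, hokE and yeaR fall short of 7 bases, and the match before lon just reaches that bound. For the copy between iap and sokX the same test gave 6 bases, AGCGCT, a length between the bounds. Both occurrences of AGCGCT fall inside the element, so they are not a repeat left on both sides by an insertion. They also held the score of this copy at 6 or more whatever bases lay beside it. The outcome of 5 or fewer was thus out of reach. The value therefore does not decide on a plain insertion there. A second search was added once that value was known. It limited how far a match could shift from one end of the element to the other, but did not require the match to cross either end. For this copy it gave 5 bases, a length that 22.6% of 10000 random pairs of positions reached. For the copies before lon and after dnaJ, hokE and yeaR it gave 13, 12, 12 and 11 bases. At most 0.01% of the random pairs reached those lengths. The results of this second search are given as values only. A deletion next to the element and recombination between copies were not tested.

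The third CRISPR array lies inside an annotated gene. The coding sequence ECD_02621 (2736170 to 2737018, 282 codons, product given as a hypothetical protein) contains all 14 units of the array, which spans 96.6% of it.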
